A study of Mus musculus with 2 samples.

How the data were processed

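Single-cell RNA sequencing of sorted mouse glioma cells gave 2 libraries in 1 group, here pool 1 and pool 2. Each library holds cells of 2 tumours mixed before capture, and the mice behind each cell were not told apart. Per the labels, 4000 cells of each pool were used for partitioning, and libraries were made from polyA RNA with the 10x Genomics 3ʹ chemistry, version 3.1 Dual Index. Reads were processed with Cell Ranger 6.0.2 on the builds GRCm38 and mm10, per the submitters' processing notes. The deposited values are raw UMI counts per gene and cell barcode, with no normalization; the cell and gene filters behind them are not given in the sources used here. Pool 1 listed 17447 genes in 3843 barcodes and pool 2 listed 17778 genes in 3650 barcodes, of which 16859 genes were in both. Every listed gene was found in at least 3 barcodes, and the lowest barcode held 501 UMIs in pool 1 and 500 in pool 2. Median depth was 6215 UMIs in pool 1 and 10086.5 in pool 2. Raw reads were not used here.

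Of the 18366 gene symbols, 18074 (98.41%) had a gene in the GENCODE vM21 annotation of GRCm38, which supplied the positions. Cells with at least 500 genes and at most 15% mitochondrial UMIs were kept, which removed 337 and 372 barcodes. Scrublet called 0 and 2 doublets, 0.029% of cells, against 2.8% and 2.62% expected from the number of cells, so doublets were not effectively removed. As an alternative, the 98 and 86 cells of highest doublet score were removed.

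The count of each gene in each cell was divided at random (binomial, probability 0.5) into a training part, used to form clusters and call cycling cells, and a held-out part, used for tests, so that no count served both. Training counts were normalized to 10000 per cell and log-transformed, 1000 variable genes were standardized within each pool, and cells were clustered on 30 principal components with 15 neighbours and the Leiden algorithm at resolution 0.8 (Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, igraph 0.11.9). Genes of the pathway lists, the sex chromosome genes, mitochondrial genes, ribosomal protein genes and core cycling genes were kept out of clustering. Clusters were named by marker lists of glial, neural, immune, vascular and erythroid cells. Only 1 glial class with enough cells received a name, so numbered clusters took the place of classes, as laid down for that case. Shares carry exact Clopper-Pearson 95% intervals.

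Held-out counts were summed per pool and cluster for the 12 clusters with at least 20 cells in each pool. Each cluster was compared with the equal-weight mean of the other 11 in 1 edgeR quasi-likelihood fit with the pool as a block (R 4.3.3, edgeR 4.0.16, limma 3.58.1; 24 libraries, 11 residual degrees of freedom, TMM, filterByExpr, 12015 genes). The 1000 genes used for clustering were left out of the calls, which left 11379 of the genes fitted. Adjusted p-values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Cycling cells had UMIs of at least 2 of 10 core genes after thinning to 2000 training UMIs, non-cycling cells had 0, and cells with 1 (313 and 259) and cells too shallow to thin (1147 and 828) stayed out. These states were compared in the 5 clusters with at least 5 cells of each state in each pool, with pool and cluster combined as the block (20 libraries, 9 residual degrees of freedom, 7731 genes, 7721 tested). Sums within a pool share the same tumours and are not independent replicates. With these blocks, p-values reflect how far differences between clusters varied between the 2 pools, or differences between states over pools and clusters. They do not extend to other tumours.

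Pathway lists were tested with camera (preset correlation 0.01 and estimated correlation) and fry, and counted over all genes and over the list alone. They were S phase, G2/M phase, hypoxia, glycolysis, MAPK output, immediate early and stress, interferon response, MHC class I and class II presentation, cholesterol synthesis, Notch, synaptic and channel genes of glioma, p53 targets, unfolded protein and integrated stress, ribosomal proteins and nuclear oxidative phosphorylation. The ribosomal list was matched by name pattern and also holds the Rps6k kinase genes. The fry p tests whether a list's genes move on balance one way and its mixed p whether they change in either direction; neither compares the list with other genes. With the preset correlation 76 list calls passed between clusters and 5 by cycling state, and with an estimated correlation 11 and 3. Levels are CPM with exact Poisson intervals. A gene with 0 counts in a cluster is given as a bound against a floor of 3 counts over both pools.

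Genes named from each contrast were those past the threshold, moved the same way in both pools and with a mean of at least 20 CPM, by largest fold each way (10 for the 3 clusters with the most cells and for cycling, 5 otherwise), together with the up to 4 list members of smallest p, leading genes of clusters, and the PDGF and sex chromosome genes. Genes named Gm with digits, ending in Rik, or of mitochondrial or ribosomal origin were left out of the naming by contrast. The text prints a part of these, and a few items are not reported here. The lists, the comparisons, the naming rule and the first set of alternatives were fixed before the data were examined. Chosen after seeing the data were the least number of 5 cells per cycling state (10 was tried first), the Jaccard index of 0.5 for matching clusters (first set lower), the least of 200 UMIs for genes listed in 1 pool only, the look at each list by pool, the removal of the highest doublet scores, and fits without clusters 1 and 7 or 9 and 10.

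Alternatives were the DESeq2 Wald test (DESeq2 1.42.0), DESeq2's size factors, no low-count filter, all counts of each cell, no replicate block, doublets kept, a stricter cell filter (1000 genes and 10% mitochondrial UMIs), resolution 0.4, another seed, other core gene numbers, 2000 variable genes, joint scaling and each pool left out in turn. The tests were tested on simulated data with 50 genes at each fold. Folds were set only on genes with enough expected counts in the compared libraries. All libraries were drawn independently from a common mean profile, with no pool effect and no other differences between clusters. The shares below thus do not extend to genes of low count or to sums that share tumours. In the contrast of cluster 11, over 12015 genes, 72% of genes set 2-fold higher, 56% of those set to 0.5-fold and 100% of those set 4-fold higher were recovered, with 3.6% of calls false. In cluster 8 these shares were 78%, 76% and 100%, with 10.8% of calls false. In the cycling contrast, over 7731 genes, 100% were recovered at each of these sizes and 2% of calls were false.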

Results

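Gene expression in sorted cells of mouse gliomas was measured by droplet single-cell RNA sequencing, as counts of unique molecular identifiers (UMIs). The tumours had been induced with PDGFB, the B chain of platelet-derived growth factor and a ligand of the receptor Pdgfra. Per the labels, the gene was transferred in utero into the embryonic telencephalon of C57BL/6 mice, tumours were taken about 40 days after birth, and cells were enriched by their GFP. There was 1 group of 2 libraries, pool 1 and pool 2, each from cells of 2 tumours mixed before capture, so n = 2 pools and there was no control group. Pool 1 held 3843 barcodes with 33.9 M UMIs, and pool 2 held 3650 barcodes with 40.9 M UMIs. After cell filters 3506 and 3276 cells remained, with medians of 7440 and 11268 UMIs. The median share of mitochondrial UMIs was 2.97% in pool 1 and 1.44% in pool 2. The comparisons address which cell populations these tumours held, which genes set each apart, and how dividing cells differed from the rest. Intervals are 95% and cover counting error only. With the pool as a block, p-values measure how far differences between clusters varied from pool to pool, not the spread between tumours. For dividing cells they measure how far the difference between states varied over clusters and pools. Each gene named below lay on the same side in both pools, except where stated.

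Genes of the oligodendrocyte precursor programme were expressed across the 11 large clusters, numbered 0 to 10. Olig2, a transcription factor of that lineage, ranged from 412 to 792 CPM in pool 1 and from 442 to 763 CPM in pool 2, against 244 and 117 CPM in microglia-like cells, which should lack it and show the level of free RNA or doublets. Cspg4 ranged from 420 to 1048 CPM and from 326 to 946 CPM, against 287 and 131 CPM. The 3 small clusters had clear identities. Cluster 11 was like committed oligodendrocyte precursors, with Enpp6 (64.7-fold over the other clusters) and Bmp4 (23.3-fold) among its leading genes, both known from cells leaving the precursor state. Cluster 12 was like microglia, with the complement genes C1qa, C1qb and C1qc, and cluster 13 was like mature oligodendrocytes, with Apod, Ptgds, Mal and Mobp. These leading genes define the clusters and were not tested.

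Cluster 11 made up 1.94% of kept cells in pool 1 (68 cells, exact Clopper-Pearson interval 1.51 to 2.45%) and 1.16% in pool 2 (38 cells, 0.822 to 1.59%), a mean of 1.55% ± 0.551 (SD, n = 2). Microglia-like cells were 0.456% (0.261 to 0.74%) and 0.488% (0.279 to 0.792%), with 16 cells in each pool. Oligodendrocyte-like cells were 0.114% (0.031 to 0.292%) in pool 1 and 0.58% (0.35 to 0.904%) in pool 2, a mean of 0.347% ± 0.329 (SD, n = 2). Cluster 4 held 10.7% of cells in pool 1 and 18.5% in pool 2, and cluster 0 held 16.4% and 11.2%. Over 8 other partitions of the same cells, clusters 9, 11 and 13 were found again in 8, clusters 10 and 12 in 7, cluster 7 in 4, cluster 1 in 3 and cluster 8 in 1. Clusters 0, 2, 3, 4, 5 and 6 were found again in none (Jaccard index of at least 0.5), so their borders are 1 of several ways to divide it. Clusters 1 and 7 held cells of low depth, with medians of 2267 and 1129 UMIs in pool 1 and of 1994 and 1423 in pool 2.

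**Figure D1:**
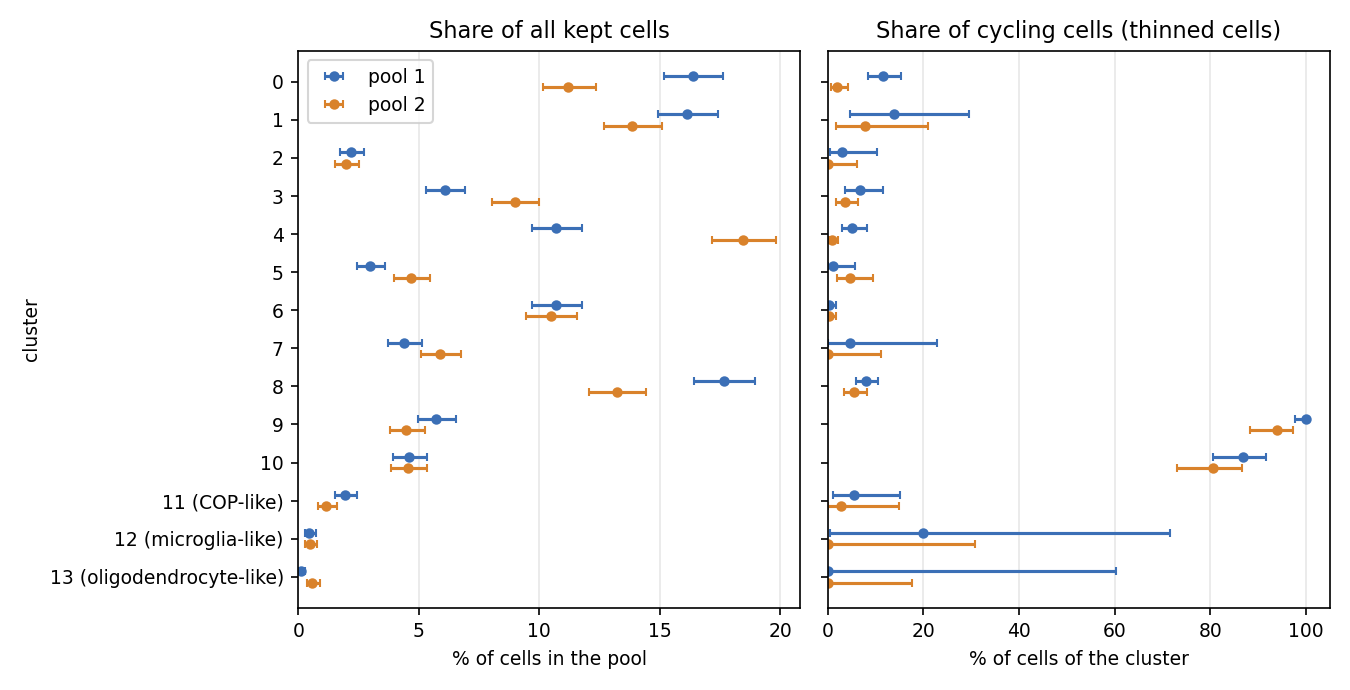
Share of kept cells in each cluster and share of cycling cells in each cluster, in percent, for pool 1 and pool 2, with 95% exact binomial intervals. Cluster 11 lies at 1.94% and 1.16% of cells, and cycling cells concentrate in clusters 9 and 10.

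Pdgfra, the receptor gene at which PDGFB acts, was lowest in cluster 11 among the 12 clusters tested. Its level there was 189 CPM in pool 1 and 239 CPM in pool 2, against 872 to 2367 CPM and 949 to 2527 CPM over the other 11 (log2 fold change −2.49 ± 0.16 SE, adjusted p = 6.92e-16, edgeR quasi-likelihood F test). Pdgfb showed the same direction (−3.28 ± 0.67, adjusted p = 0.000208). It had 3 and 4 UMIs in cluster 11 over all counts, of which only the held-out part was tested. Pdgfa, whose product also binds Pdgfra, had the opposite pattern, with 162 and 136 CPM in cluster 11 against at most 32.7 and 34.3 CPM in the other tested clusters (2.98 ± 0.22, adjusted p = 4.4e-14). In the small clusters not tested, Pdgfa stood at 97.5 and 223 CPM in oligodendrocyte-like cells and at 71.7 and 61.9 CPM in microglia-like cells. In GRCm38, Pdgfra lies on chromosome 5 from 75152292 to 75198215, Pdgfb on chromosome 15 from 79995874 to 80014977, and Pdgfa on chromosome 5 from 138976014 to 138997370. With cells thinned to an equal depth of 2000 UMIs, a Pdgfra UMI was found in 85.6% and 89.9% of all glial cells but in 16.4% (7.77 to 28.8%) and 22.9% (10.4 to 40.1%) of cluster 11. Microglia-like cells, which should lack Pdgfra, gave 20% (0.505 to 71.6%) and 40% (12.2 to 73.8%) on 5 and 10 cells. Their cluster was shallower before thinning, with medians of 1955.5 and 6559 UMIs against 12172.5 and 14536 in cluster 11. The share of free RNA can depend on depth, so this comparison could not tell Pdgfra UMIs in cluster 11 from free RNA. Pdgfb was detected in 5.43% and 6.63% of thinned glial cells, and its highest level was in microglia-like cells, at 272 and 110 CPM. Pdgfrb was listed for pool 2 only. No feature of the transferred gene construct was listed, so Pdgfb counts from the mouse gene and from the transferred gene were not told apart.

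**Figure D2:**
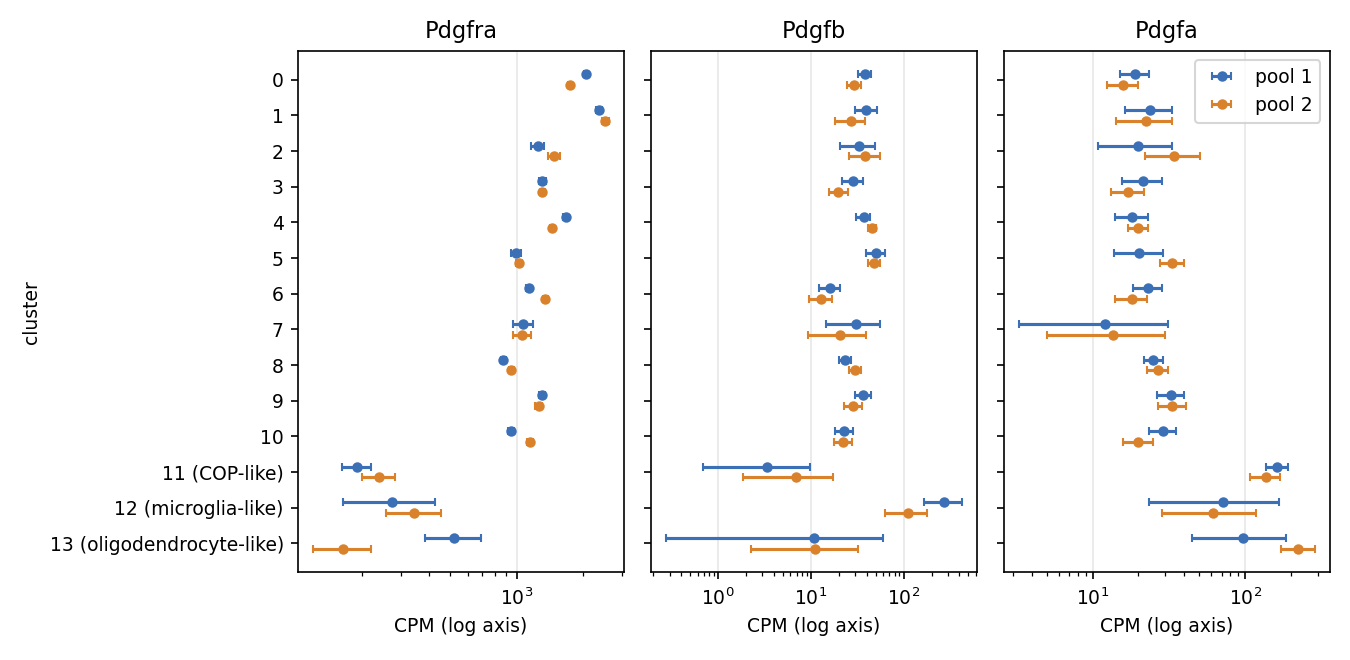
Levels of Pdgfra, Pdgfb and Pdgfa in CPM on a log axis, for each cluster and pool, with 95% Poisson intervals. In cluster 11 Pdgfra lies at 189 and 239 CPM, below every other tested cluster, while Pdgfa lies at 162 and 136 CPM, above them.

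Cluster 11, found again in 8 of 8 other partitions, had genes with large folds. Bfsp2, a beaded filament gene on chromosome 9 from 103424924 to 103480420, was 117-fold higher (log2 6.88 ± 0.19, adjusted p = 2.37e-28). Its log2 values by pool, computed with a small prior count, were 6.21 and 6.54, both below the fitted one. Cluster 9, which is in the reference, held 1 count of Bfsp2. Chn2, which encodes a Rac GTPase-activating protein, was 25.4-fold higher (4.67 ± 0.11, adjusted p = 1.52e-29), and Fa2h, an enzyme of myelin lipid synthesis, 23.7-fold (4.57 ± 0.24, adjusted p = 8.04e-19). Rasgef1b was also higher (5.09 ± 0.25), as was Mycl (5.21 ± 0.21), which had served to name the cluster. Without a count in cluster 11, Rasgrf1 was at least 8.20-fold lower and Vit at least 6.91-fold lower, taking 3 counts over both pools as the floor. Hist1h4i was at least 5.52-fold lower, although reads are hard to place among histone copies. On 1 count, Sorcs2 was 27.3-fold lower (4.89 to 1076) and Cntnap5b 22.3-fold (4.01 to 882). Among the 11379 genes tested, 1368 were higher and 1002 lower in cluster 11 than in the mean of the other 11 clusters (edgeR quasi-likelihood, Benjamini-Hochberg, 24 libraries from the 2 pools), and 789 and 778 of these by at least 2-fold.

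Feedback and target genes of MAPK signalling were low in cluster 11. Ccnd1, which drives entry into the cell cycle, was lower by a log2 change of −2.63 ± 0.17 (adjusted p = 5.15e-16), and the MAPK feedback genes Spry4 and Spry1 by −2.44 ± 0.25 and −2.70 ± 0.28. Phlda1 was lower by −2.18 ± 0.19 (adjusted p = 1.75e-12). Of the 14 MAPK output genes tested, 12 were lower and 1 higher (13 and 1 adjusted over the list alone), with a median of −2.44, or −2.28 with genes without counts at their bound. The exception was Epha4, at 2.56 ± 0.31 (adjusted p = 1.2e-08), named after its values were seen. The list was lower than other genes (camera, preset correlation 0.01, adjusted p = 1.44e-10; adjusted p = 0.0253 with an estimated correlation), and its members moved on balance one way (fry, adjusted p = 2.33e-06). Synaptic and channel genes were lower for 10 of 20 (11 lower and 1 higher adjusted over the list alone), including Kcnip3, whose product binds potassium channels (−2.39 ± 0.22) and the channel gene Kcnd2 (−2.30 ± 0.21). p53 targets were lower for 5 of 13 (6 lower and 1 higher adjusted over the list alone), among them Eda2r (−2.28 ± 0.60) and Cdkn1a (−1.21 ± 0.34). These last lists passed with the preset correlation (adjusted p = 0.000266 and 0.0207) and not with an estimated one (0.164 and 0.311). Notch genes were lower for 3 of 9, including Notch1 (−0.96 ± 0.21), and did not pass as a list (camera adjusted p = 0.164).

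MAPK output genes were higher in cluster 4, at a smaller size, against a reference that holds cluster 11, where they were low. Spry1 (log2 0.69 ± 0.12, adjusted p = 0.000289), Dusp6 (0.69 ± 0.12), Spry4 (0.58 ± 0.11) and Etv4 (0.53 ± 0.11) were higher, and 9 of 14 MAPK output genes were higher with 0 lower (11 and 0 adjusted over the list alone). The list's median was 0.475 (camera adjusted p = 4.89e-09; adjusted p = 0.038 with an estimated correlation; fry adjusted p = 0.000172). With the preset correlation the list was also higher in clusters 0, 1, 2 and 5, with medians of 0.333, 0.379, 0.39 and 0.427, and in none of these with an estimated correlation (adjusted p = 0.383, 0.369, 0.122 and 0.169), except cluster 2 without the low-depth clusters 1 and 7 (0.0372). Rasgrf1, an activator of Ras, was higher by 1.52 ± 0.26 (adjusted p = 0.000188), Lpo by 1.36 ± 0.20 (adjusted p = 2e-05), and Cdkn2b, an inhibitor of cyclin-dependent kinases on chromosome 4, by 1.11 ± 0.13 (adjusted p = 1.41e-06). By pool, Lpo stood at 0.71 and 1.75 and Rasgrf1 at 0.82 and 1.35, for Rasgrf1 both below the fitted value. The reference holds cluster 11, where Rasgrf1 had 0 counts. Rasgrf1 was also higher in cluster 5 (2.40) and cluster 8 (1.27). Ube2c (−2.33 ± 0.29) and Birc5 (−2.14) led the lower genes, and 29 of 53 G2/M genes (36 adjusted over the list alone) and 17 of 41 S phase genes (23 adjusted over the list alone) were lower. Both lists passed with an estimated correlation (adjusted p = 0.00483 and 0.0101). The cycling clusters 9 and 10 are in the reference, which raises the level that cell-cycle genes are compared with. In cluster 4, 429 genes were higher and 203 lower of 11379, against 364 higher and 37 lower when clusters 9 and 10 were left out of the fit, and without the pool in the model 159 passed in place of 632.

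Cluster 5 had high levels of genes known to respond to low oxygen. Bnip3, on chromosome 7 from 138890836 to 138909519, was higher by log2 2.30 ± 0.19 (adjusted p = 5.24e-12), the angiogenic factor Vegfa by 2.10 ± 0.19 (adjusted p = 9.14e-11), the glucose transporter gene Slc2a1 by 2.62 ± 0.31 and Fam162a by 1.23 ± 0.14. The size differed between pools. Log2 values in pool 1 and pool 2 were 0.78 and 2.98 for Slc2a1, 1.33 and 2.50 for Vegfa and 1.54 and 2.58 for Bnip3. In pool 1 Vegfa was higher in cluster 1 (107.4 CPM) than in cluster 5 (86.9 CPM). In pool 2 it was highest in cluster 5 (161.9 CPM). Of 21 hypoxia genes, 17 were higher (19 adjusted over the list alone; median 1.23; camera adjusted p = 7.77e-23; adjusted p = 0.00483 with an estimated correlation). Of 12 glycolysis genes, 10 were higher (11 adjusted over the list alone), including Gpi1 (1.63 ± 0.13) and Ldha (1.37 ± 0.11), with camera adjusted p = 1.16e-19 (adjusted p = 0.0491 with an estimated correlation, and 0.0889 without the low-depth clusters 1 and 7). Pdlim4 (3.03 ± 0.20, adjusted p = 2.04e-14) and S100a10 (2.99 ± 0.13, adjusted p = 4.69e-20) were also higher, and Sez6, a gene of neuronal cells, was lower by −2.82 ± 0.43. In all, 691 genes were higher and 254 lower, and 511 in place of 945 passed without the pool in the model. The median depth of cluster 5 was 13809 UMIs in pool 1 and 21696 in pool 2, above that of most clusters.

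The p53 target Cdkn1a, which halts the cell cycle, was also higher in cluster 5 (log2 1.71 ± 0.16, adjusted p = 2.14e-10), with 8 of 13 targets higher (10 adjusted over the list alone) and camera adjusted p = 4.15e-07, which did not pass with an estimated correlation but did without the low-depth clusters 1 and 7 (adjusted p = 0.0337). Cholesterol synthesis genes were lower for 5 of 22 (11 adjusted over the list alone), among them Stard4 (−1.34 ± 0.26) and Fdft1 (−0.89 ± 0.22), with camera adjusted p = 7.85e-08 (adjusted p = 0.303 with an estimated correlation). The interferon list was higher for 13 of 17 (15 adjusted over the list alone; camera adjusted p = 3.04e-07; adjusted p = 0.348 with an estimated correlation), and this rested on pool 2. Ifit3 stood at log2 −0.08 in pool 1 and 4.18 in pool 2, and Isg15 at −0.20 and 3.99, so neither moved the same way in both. The MHC class I list was higher for 5 of 13 (8 adjusted over the list alone; adjusted p = 0.000382, and 0.275 with an estimated correlation), including B2m (0.54 ± 0.13), and its median was 0.0 in pool 1 and 0.69 in pool 2, so it too rested largely on pool 2. The immediate early gene Fos was higher by 0.79 ± 0.15 while its list did not pass (adjusted p = 0.113). Only 2 members of the MHC class II list could be tested, too few for a list test.

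**Figure D3:**
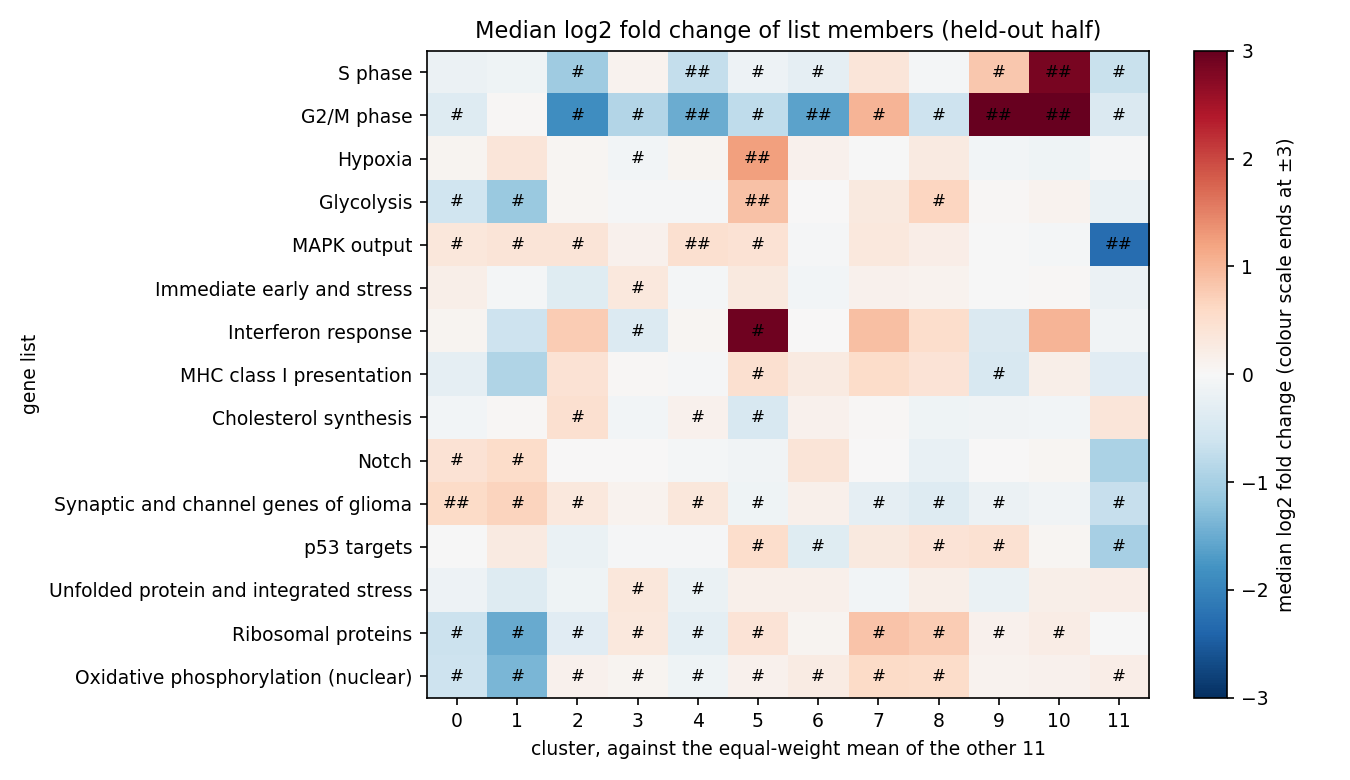
Median log2 fold change of each fixed gene list in each cluster against the mean of the other clusters, as a heat map whose colours end at −3 and 3. A single mark shows lists past the threshold with the preset correlation of 0.01 and a double mark those also past it with an estimated correlation, such as MAPK output in clusters 11 and 4 and hypoxia in cluster 5.

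**Figure D4:**
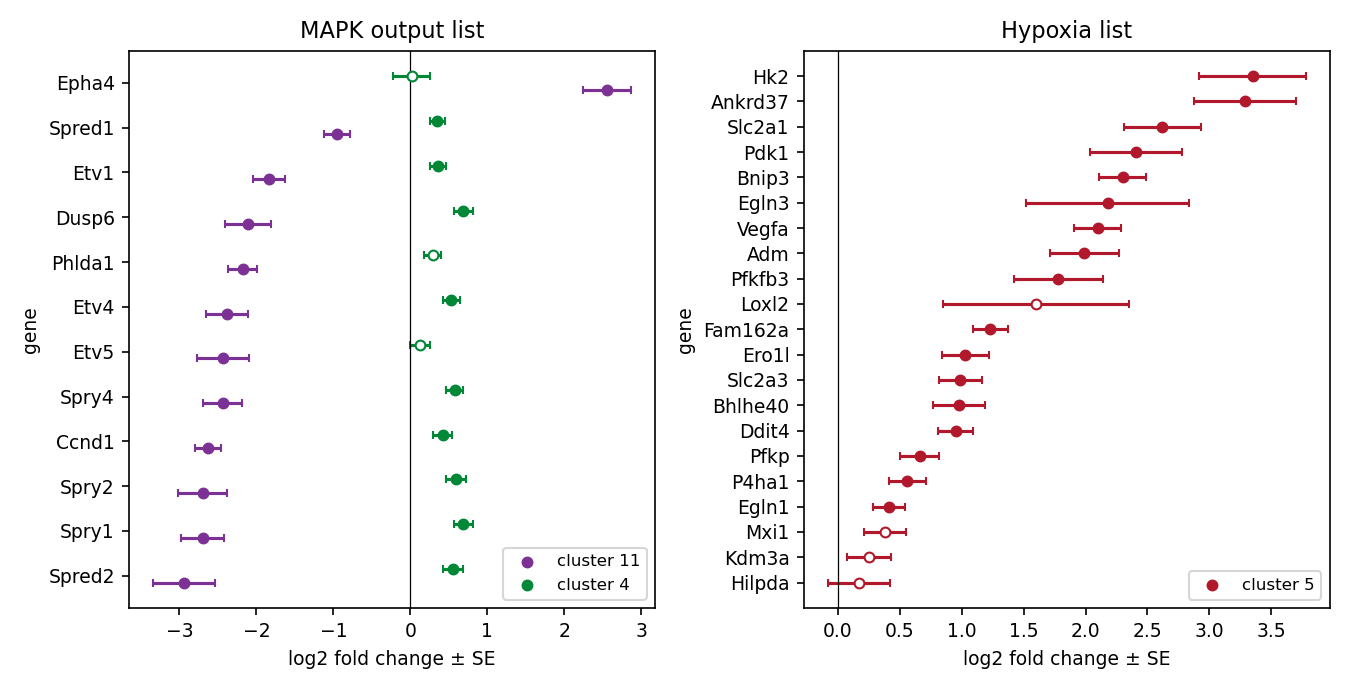
Log2 fold changes with SE of MAPK output genes in clusters 11 and 4 and of hypoxia genes in cluster 5, filled where past the adjusted threshold. In cluster 11 the feedback gene Spry1 lies at −2.70 and in cluster 4 at 0.69, and 2 MAPK output genes without counts in cluster 11 are left out.

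Synaptic and channel genes were higher in cluster 0, and with the preset correlation also in clusters 1, 2 and 4. In cluster 0 the sodium channel genes Scn1a (log2 1.02 ± 0.15, adjusted p = 1.92e-05) and Scn3a (0.61 ± 0.11), the calcium channel gene Cacna1a (0.69 ± 0.13) and Kcnd2 (0.58 ± 0.10) were higher. Of 20 list members, 16 were higher and 0 lower (18 adjusted over the list alone; median 0.574; camera adjusted p = 3.38e-09; adjusted p = 0.0318 with an estimated correlation). In cluster 1 the median was larger, at 0.668, with 13 of 20 higher (14 adjusted over the list alone; camera adjusted p = 4.49e-07), and in cluster 4 it was 0.34, with 6 higher (12 adjusted over the list alone; camera adjusted p = 4.29e-07). In cluster 2 only 3 of 20 passed. With an estimated correlation none of these 3 clusters passed, except cluster 4 without the low-depth clusters 1 and 7 (adjusted p = 0.0372). The long noncoding RNA gene Miat was higher by 1.59 ± 0.21 (adjusted p = 5.52e-06), and S100a10 (−1.78 ± 0.25, adjusted p = 7.55e-06), Lgals1 (−1.91 ± 0.43) and Cdkn1a (−1.30 ± 0.21) were lower. The Notch genes Hey2 (1.06 ± 0.28) and Dll1 (0.74 ± 0.21) were higher, with camera adjusted p = 0.0463 for the list, and 0.198 with an estimated correlation. Oxidative phosphorylation genes were lower for 76 of 83 and ribosomal protein genes for 79 of 90, both past the preset test and neither past the estimated one (0.191 and 0.23). Of 11379 genes, 1519 were higher and 1630 lower, and 1853 in place of 3149 passed without the pool in the model. Mitochondrial RNA was 4.1% and 2.49% here, above the pool medians, and median depth was 4755 UMIs in pool 1 and 10359 in pool 2, against 7440 and 11268 over all kept cells. The nuclear RNA Malat1 stood at 79120 and 61910 CPM in cluster 0, above every other tested cluster except cluster 1.

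Clusters 1 and 7 joined low depth with uneven RNA content. In cluster 1 the nuclear RNA Malat1 reached 105100 and 116700 CPM, higher by log2 1.35 ± 0.17 (adjusted p = 2.83e-08), and Miat was higher by 1.96 ± 0.28. Naa38 (−2.46 ± 0.25, adjusted p = 8.02e-10) and Rangrf (−2.88 ± 0.47) were among the lower genes, and 82 of 90 ribosomal protein genes and 77 of 83 oxidative phosphorylation genes were lower (adjusted p = 0.111 and 0.122 with an estimated correlation). In cluster 7 the ribosomal protein genes were instead higher for 78 of 90 (camera adjusted p = 9.54e-94, not past the threshold with an estimated correlation), as were Cks2 (2.10 ± 0.33, adjusted p = 2.88e-05) and Ccna2 (2.51 ± 0.60). Of 11379 genes, 1703 were higher and 2149 lower in cluster 1, and 345 and 104 in cluster 7. These moved to 1100 and 1370 in cluster 1 at Leiden resolution 0.4, and in cluster 7 to 119 and 22 with the highest doublet scores removed and to 243 and 48 with another seed.

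Cluster 8 was marked by S100a10 (log2 2.29 ± 0.12, adjusted p = 9.57e-17) and Lgals1 (2.29 ± 0.21, adjusted p = 9.24e-10), an S100 family gene and a galectin gene, both of which were low in cluster 0. Tnfrsf12a, a TNF receptor family gene, was also higher (1.34), and the clock gene Per3 was lower (−1.80 ± 0.29, adjusted p = 1.95e-05). Of 12 glycolysis genes 10 were higher, including Ldha (1.03 ± 0.11), as were 82 of 90 ribosomal protein genes and 76 of 83 oxidative phosphorylation genes. The p53 targets Cdkn1a (0.88 ± 0.16) and Ccng1 (0.68 ± 0.13) were higher and the glutamate receptor gene Gria4 was lower (−0.68 ± 0.14). None of these lists passed with an estimated correlation (adjusted p = 0.174, 0.169, 0.211, 0.249 and 0.14 for glycolysis, ribosomal protein, oxidative phosphorylation, p53 and synaptic genes). In cluster 8, 1966 genes were higher and 953 lower, with 1571 in place of 2919 without the pool in the model. In simulated data 10.8% of calls in this contrast were false, above the 5% aimed at.

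Cluster 2 held 142 cells. Meox1, a homeobox gene on chromosome 11, was higher by log2 3.75 ± 0.21 (adjusted p = 2.29e-16), Gng11 by 3.77 ± 0.29 (adjusted p = 2.37e-12) and the glycolytic and astrocytic gene Aldoc by 2.28 ± 0.16 (adjusted p = 7.39e-13). Lhx2, a forebrain transcription factor gene, had 0 counts and was at least 6.33-fold lower. After their values were seen, some further genes were singled out, not as a tested list: Irx5 (5.56 ± 0.57), Pax3 (5.39 ± 0.66) and Hotairm1 (3.66 ± 0.36) were higher. Pdgfra and Olig2 stood at 0.911 or more of their mean in the other 10 large clusters. The AMPA receptor gene Gria4 was higher (1.74 ± 0.14, adjusted p = 1.38e-11), and 3 of 20 synaptic genes were higher (6 adjusted over the list alone; camera adjusted p = 0.000382, and 0.166 with an estimated correlation). Cholesterol synthesis genes were higher for 4 of 22 (9 adjusted over the list alone; adjusted p = 0.531 with an estimated correlation), with list medians of −0.06 in pool 1 and 0.90 in pool 2. G2/M genes were lower for 20 of 53 (31 adjusted over the list alone; camera adjusted p = 5.8e-22, not past the threshold with an estimated correlation, but past it without the low-depth clusters 1 and 7, at 0.0384), against a reference that holds the cycling clusters 9 and 10. In all, 362 genes were higher and 142 lower, against 307 and 59 with clusters 9 and 10 left out of the fit, and 270 in place of 504 passed without the pool in the model.

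The leading genes of clusters 3 and 6 included genes known from astrocytes and radial glia, namely Sox9 (3.3-fold), Vim (2.2-fold) and Fabp7 (1.8-fold) in cluster 3 and Gja1 (3.0-fold) and Aqp4 (2.3-fold) in cluster 6. Gja1 and Aqp4 were low there, at 20.7 and 17.1 CPM, and Vim stood at 2.5-fold in cluster 8. The precursor markers Rlbp1 and C1ql1 were also leading genes of clusters 3 and 6. Of the marker lists, cluster 6 stood highest for oligodendrocyte precursors (median log2 0.56) and cluster 3 for neural stem cells or radial glia (0.3). Cycling cells stood at 6.74% and 3.53% of cluster 3 and at 0.3% of cluster 6 in each pool. In cluster 6 the potassium channel subunit gene Kcnmb4 (log2 1.99 ± 0.16, adjusted p = 1.52e-11), Pcp4 (1.78 ± 0.14, adjusted p = 1.3e-11) and C1ql1 (1.60 ± 0.21) were higher, and Mki67 (−2.84 ± 0.37), a marker of dividing cells, and Cdkn1a (−1.69 ± 0.23, adjusted p = 1.13e-06) were both lower. Of 53 G2/M genes, 35 were lower (40 adjusted over the list alone; adjusted p = 0.0215 with an estimated correlation). In cluster 3, Moxd1 (1.30 ± 0.20, adjusted p = 0.000977), Cd93 (1.19 ± 0.19) and the retinoid-binding gene Rlbp1 (1.18 ± 0.20) were higher, and Nde1 was lower (−1.87 ± 0.31). The stress gene Xbp1 was higher by 0.56 ± 0.13, the 1 of 14 unfolded protein genes to pass (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.339 with an estimated correlation), and 0 of 20 immediate early genes passed (8 higher adjusted over the list alone; adjusted p = 0.249 with an estimated correlation). Genes higher and lower numbered 951 and 378 in cluster 6 and 49 and 22 in cluster 3. With the cycling clusters 9 and 10 left out of the reference, those of cluster 6 numbered 770 and 227. Without the pool in the model 604 in place of 1329 passed in cluster 6, and 7 in place of 71 in cluster 3.

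Dividing cells formed clusters 9 and 10. In cluster 9 the mitotic genes Kif2c (log2 6.87 ± 0.22) and Hmmr (6.03 ± 0.16, adjusted p = 1.47e-29) were higher. Higher in cluster 10 were Esco2 (5.77 ± 0.20) and Aurkb (5.60 ± 0.19, adjusted p = 6.41e-25), while Cdkn2b was lower there (−1.70 ± 0.22, adjusted p = 3.84e-08). The fitted values of Kif2c, Hmmr, Esco2 and Aurkb lay above those of both pools, which were 5.64 and 5.74 for Kif2c. All 53 G2/M genes were higher in both clusters (adjusted p = 0.000365 and 0.000508 with an estimated correlation). S phase genes set the 2 clusters apart. In cluster 10 all 41 passed, with medians of 2.91 and 2.57 by pool, and in cluster 9 23 of 41, with 0.51 and 0.78. Without the low-depth clusters 1 and 7, the S phase list passed in cluster 10 (camera with an estimated correlation, adjusted p = 0.00197) and not in cluster 9 (0.197). Since other cell-cycle genes drove these clusters, such calls (2209 and 2155 genes) are not independent evidence of division. With cells thinned to 2000 UMIs, 18.4% of glial cells in pool 1 (431 of 2339, 16.9 to 20.1%) and 12.2% in pool 2 (294 of 2413, 10.9 to 13.6%) had UMIs of at least 2 of 10 core cycling genes, a mean of 15.3% ± 4.41 (SD, n = 2). Cycling cells were 100% and 93.9% of cluster 9 and 86.8% and 80.6% of cluster 10, against 0.3% of cluster 6 in each pool. In cluster 0 the share was 11.6% in pool 1 and 1.85% in pool 2. Cluster 11 held 5.45% (3 of 55 cells, 1.14 to 15.1%) and 2.86% (1 of 35 cells, 0.072 to 14.9%), too few cells for a firm share. Free RNA of core genes was not subtracted, so it remains open whether it adds to the difference between pools.

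Cycling cells were then compared with non-cycling cells of the same pool and cluster, in clusters 0, 3, 4, 8 and 10, which held enough cells of both states. Cluster 9 and the other 6 clusters of the class fit were not in this comparison. In cluster 10, 138 and 116 cells were cycling but only 9 and 10 were non-cycling in pool 1 and pool 2. Without thinning, 98.1% and 99.3% of its cells had at least 2 core genes. Its non-cycling state thus rested on the thinning. In pool 2, clusters 0 and 4 held 5 cycling cells each. Cenpa, a centromere histone gene on chromosome 5 from 30666777 to 30674830, was 20.9-fold higher (log2 4.39 ± 0.23, adjusted p = 2.41e-29). Kif4 (4.20 ± 0.47) and the kinase gene Pbk (3.45 ± 0.18) were also higher. For Kif4 the values by pool were 2.59 and 3.34, both below the fitted one. The lower genes included the amino acid transporter gene Slc7a10 (−1.21 ± 0.32, adjusted p = 0.0137), Lss (−1.14 ± 0.32, adjusted p = 0.0261), Pik3ip1 (−1.11 ± 0.26) and the mitophagy kinase gene Pink1 (−1.06 ± 0.22, adjusted p = 0.000518). Cholesterol synthesis genes were lower for 4 of 21 (9 adjusted over the list alone), namely Fdps (−0.48 ± 0.13), Hmgcs1 (−0.43 ± 0.12), Lss and Sc5d (−0.68 ± 0.21). By pool, Lss stood at −0.92 and −2.80 and Slc7a10 at −1.39 and −2.16. The cholesterol list passed with both correlations (camera adjusted p = 7.03e-07; adjusted p = 0.0297 with an estimated correlation; fry adjusted p = 0.00826). G2/M genes were higher for 19 of 24 (21 adjusted over the list alone; adjusted p = 6.33e-06 with an estimated correlation) and S phase genes for 7 of 29 (14 adjusted over the list alone; 0.0297), including Rrm2 (2.31 ± 0.23) and Atad2 (1.32 ± 0.17). Rrm2 stood at 2.70 in pool 1 and 0.44 in pool 2. Since the cells were chosen by other cell-cycle genes, Cenpa, Kif4 and these lists are not independent evidence of division. Cdkn1a was also higher in cycling cells (0.48 ± 0.13, adjusted p = 0.0213). Of 7721 genes, 151 were higher and 126 lower (410 cycling and 2367 non-cycling cells, 20 libraries from the 2 pools), and both numbers depended on the setting. The split was 160 and 86 with DESeq2's size factors, 94 and 44 with the DESeq2 Wald test, 181 and 54 at 3 core genes, 210 and 62 with another seed, and 105 and 22 with the stricter cell filter. It was 130 and 104 with the highest doublet scores removed and 113 and 113 without clusters 9 and 10. With at least 1 cell of each state it turned, at 88 higher and 109 lower.

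Pool 1 and pool 2 were compared by size alone, since each is 1 library. Of 4185 genes at 50 CPM or more, 21 differed by at least 2-fold, and log2 CPM had a Pearson correlation of 0.973 and a Spearman correlation of 0.957 across genes, which are not independent replicates. Xist was listed for pool 1 only and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty for pool 2 only, so sex and pool were confounded. The metallothionein gene Mt2 was 13.03-fold higher in pool 2, at 182.5 CPM there, Mt1 3.77-fold, and the cold-inducible RNA-binding protein genes Cirbp 3.40-fold (39.8 against 135 CPM) and Rbm3 3.16-fold (136 against 431 CPM), each in 12 of 12 clusters. In pool 1, Pmepa1 was 3.09-fold higher, the mitochondrial gene mt-Cytb 2.27-fold, the complement gene C4b 2.13-fold and the endoplasmic reticulum chaperone gene Hspa5 2.11-fold. Tsix, antisense to Xist, had 4099 UMIs in pool 1 and 3 in pool 2, and 3′ reads of overlapping genes are hard to assign. Cirbp lies on chromosome 10 from 80165985 to 80172786 and Rbm3 on chromosome X from 8138975 to 8145880.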

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

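The test of cell make-up for Cirbp was chosen after the result was seen; those of time of day and temperature were written down before their values were looked at. The design gives 1 group, so no biological explanation was tested, and sex, mice and library are confounded with the pool.

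Some genes were listed in the table of only 1 pool although their UMIs in glial cells there exceeded what a count of 0 allows. In pool 1, Xist had 59925 UMIs and was found in 91.7% of glial cells. In pool 2 such genes included the Y-linked genes Ddx3y with 1840 UMIs, Eif2s3y with 1482, Kdm5d with 1111 and Uty with 1015, and the haemoglobin genes Hbb-bs with 1330 and Hba-a2 with 466. Of the haemoglobin UMIs, 1327 and 462 lay in 1 cell. Xist and the Y-linked genes separate the pools by sex, and the tumours of a pool were not told apart.

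Cirbp and Rbm3 were higher in pool 2 in 12 of 12 clusters. With an equal number of cells of each cluster, Cirbp was still 3.267-fold higher, so the shares of these clusters do not account for it. A different make-up within clusters was not tested. A different time of day could act on clock genes, whose median absolute log2 ratio was 0.274 over 15 genes, under the bound of 0.32 for no such cause. Its interval of 0.192 to 0.35 crosses that bound, so this stays open. The demand that the whole interval lie beyond the bound was added after the value was seen. Over 13202 genes with at least 30 UMIs in each pool the median was 0.159, with a small constant added to the levels. The prediction for such a cause also asked for Dbp and Arntl in opposite directions. Both were lower in pool 2, by −0.278 and −0.014. A different temperature before or during collection also stays open, with a median of −0.182 (−0.341 to −0.013) for 16 heat shock targets, between its bounds of −0.32 and 0.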

How the results depend on the processing

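Fits without clusters 1 and 7, without clusters 9 and 10, with the highest doublet scores removed, with 10 or 1 cells per state, and shares with another seed were chosen after seeing the data. Of 167 counts and shares recomputed, 139 stayed within 1.5 times or 1 SD and 28 moved. Of a further 105 shares, of numbered clusters and of cycling cells within clusters, 73 stayed and 32 moved. The number of genes passing moved as follows. With the DESeq2 Wald test it was 45 in cluster 3 and 138 for cycling. Without the low-count filter it was 225 in cluster 3 and 465 for cycling, where more genes are tested. With all counts of each cell, for genes past the threshold, cluster 2 gave 875 and cluster 3 gave 177, and again for genes past the threshold, cluster 7 gave 857, with 533 for cycling, where the tested counts both formed the clusters and were deeper, and these were not separated. With no replicate block it was 1853, 270, 7, 159, 511, 604 and 1571 in clusters 0, 2, 3, 4, 5, 6 and 8, and differences between pools then count as spread. The cycling contrast then gave 199 genes higher and 42 lower. With the stricter cell filter it was 127 for cycling (105 higher and 22 lower). At Leiden resolution 0.4, for genes past the threshold, cluster 1 gave 2470, with 590 for cycling. With another seed it was 291 in cluster 7, and with the highest doublet scores removed 141 in cluster 7. With genes used for clustering also called it was 129 in cluster 3, where more genes are tested. Without the cycling clusters 9 and 10 it was 401 in cluster 4 (364 higher and 37 lower). With at least 10 cells of each state it was 115 for cycling, where fewer libraries remain. The microglia-like share was 0.43% with doublets kept and 0.444% with joint scaling and with another seed. List calls with an estimated correlation numbered 11 between clusters and 3 by cycling state, and the estimated correlations were mostly above the preset of 0.01. For the remaining settings the cause was not tested. Leaving out 1 pool gave 1.16 to 1.94% for the cluster 11 share, 0.456 to 0.488% for microglia-like cells, 0.114 to 0.58% for oligodendrocyte-like cells and 12.2 to 18.4% for cycling cells. Of 1920 recomputed values of named genes, 1643 stayed, 104 and 106 of them folds with 1 pool left out, where there was no call to keep. A further 146 lost the call, 130 (all with 1 pool left out) moved, and 1 reversed: Csgalnact1 in cluster 1, higher in the report's partition by 1.35, stood at −0.27 at resolution 0.4, and the cause was not tested. Of 309 list values, 202 kept their call and 107 lost it. Clusters without a match in an alternative partition gave no value, and with 1 pool there is no test. Depth limits cluster 11, with 106 cells, where 36% of genes set 1.5-fold higher in simulated data were recovered, and the low-depth clusters 1 and 7.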

Other observations

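The look at other cell types, at Gpr17 and Cdkn1a, and at recurrence over partitions was chosen after the results were seen.

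Cirbp and Rbm3 also differed between the pools in the few cells of other types. In microglia-like cells Cirbp stood at 14.3 and 117 CPM and Rbm3 at 71.7 and 351 CPM in pool 1 and pool 2, and in oligodendrocyte-like cells at 43.3 and 183 CPM and at 32.5 and 270.5 CPM. These rest on as few as 1 UMI of Cirbp in pool 1. Among clock genes, Per1 had a log2 ratio of pool 2 over pool 1 of 0.90, Arntl of −0.01 and Dbp of −0.28. Among heat shock targets, 12 of 16 were lower in pool 2, while Hspa1a was higher by 1.23.

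Gpr17, known from precursors on the way to oligodendrocytes, reached 1726 and 1656 CPM in cluster 11 and at most 512 and 467 CPM in the other tested clusters. In the oligodendrocyte-like cells Gpr17 stood at 184 and 18.3 CPM. Cdkn1a was highest in these cells in pool 2, at 1429 CPM, and stood at 21.7 CPM in pool 1, on 4 cells there and 19 in pool 2.

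Cells with training UMIs of at least 2 of the regional genes Irx2, Irx3, Irx5, Pax3 and Hotairm1 made up 24.7% and 40.0% of cluster 2 (19 and 26 cells). They made up 1.41% and 1.37% of glial cells outside clusters 2 and 11. By number, more lay outside cluster 2, with 47 and 43 cells, 25 of them in cluster 4 of pool 2. These genes lead cluster 2 in the same training counts, so its higher share was fixed in advance and is not a test.

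Over 5 other partitions, a cluster with lower MAPK output genes was found in 5 with the preset correlation and in 3 with an estimated correlation. Clusters with higher hypoxia genes were found in 5 and 2, with higher MAPK output genes in 5 and 1, and with higher synaptic genes in 5 and 2. Any cluster of a partition was allowed to count, so these are weak tests of recurrence.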
